A study of Cucumis melo with 12 samples.

How the data were processed

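Messenger RNA levels were measured in melon (Cucumis melo) leaves of 2 varieties, 162 and 13-5A, at 0 h and 12 h of exposure to 4 °C. The labels name the 4 °C treatment for the 0 h samples too and do not give their temperature before sampling; 0 h is read here as the start of exposure. Each of the 4 groups had 3 libraries, which gave 12 libraries in all. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a VAHTS Universal V6 kit, and paired-end reads were generated on an Illumina NovaSeq instrument. The labels do not say that the libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

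The values deposited by the authors are FPKM, that is, fragments scaled by gene length and library total, for 21691 genes. The aligner, the counting program, the genome build and the annotation are not given in the sources used here. Columns were assigned to samples by the sample descriptions in the labels, and 0 further columns of per-sample values were present. Gene identifiers are given as in the deposited table, without names. None of them matched the name table at hand, which describes the assembly USDA_Cmelo_AY_1.0 (0 identifiers matched). The 39 gene lists and cell type markers fixed before the data were examined were therefore neither matched nor tested, and neither were their alternatives.

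FPKM hide the depth, so it was recovered from the values. Each value equals a whole number of reads, times a constant, divided by the gene length and by the library total, and lengths and totals were solved for jointly. In the tested genes 100% of the values came out whole within 0.001 reads. Totals ran from 41299369 to 45355323 per library; whether a unit is a read or a read pair was not resolved. At the median gene length of 1645 bases, 1 FPKM corresponds to about 72 reads. On simulated data the totals of 12 of 12 libraries and the lengths of 99.9% of 1716 genes were recovered exactly. Intervals or floors from these reads cover counting error only.

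FPKM were transformed to log2(FPKM + 1), and the 15592 genes with a mean of at least 1 FPKM over the 12 libraries were tested. The model was limma 3.58.1 in R 4.3.3 with an intensity trend, fitted to all 12 libraries with the 4 groups as the only term and 8 residual degrees of freedom. There were 5 comparisons: 12 h against 0 h in each variety, the difference between these effects (the interaction, 162 effect minus 13-5A effect), and 162 against 13-5A at each time. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 difference was at least 1 in size, a 2-fold change. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

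The model was tested on simulated data built on 15592 genes. For the comparison of times in 162 it recovered 79% of 100 genes changed 3-fold and 98% of 100 changed 6-fold, with 2 unchanged genes called. For the interaction it recovered 58% and 92%, with 5 unchanged genes called. Simulated reads were drawn independently for each gene and library. Only the genes counted above as changed differed, as many up as down, and only in 162 at 12 h. They were not drawn from the genes with the fewest reads, so recovery among those was not measured. Far more genes changed in the real data, so the false calls there may be more numerous. With residuals of the real data shuffled, as described below, up to 520 interactions were called. Those residuals still held any real interaction, so 520 is not a count of false calls.

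Because the identifiers carry no names, at most 2 genes per direction and comparison are named by rule. By that rule, written before the data were examined, they are the called genes with the largest differences among those with a mean of at least 5 FPKM. Outside the interaction, the libraries of the compared groups also had to be free of overlap. Genes named outside this rule, the most abundant gene among them, were chosen after their values were seen. Counts of reads in pairs of libraries of one group differed far beyond sampling noise (chi-square per gene 37.6 to 263), so all libraries were kept as separate.

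The alternatives planned beforehand were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, equal totals in every library (TPM), median-ratio scaling, limma without the trend, no fold minimum, only the compared groups, a replicate block, and each library left out. Chosen after seeing the data were limma voom on the recovered reads, rescaling without the 10 highest genes, removal of the gene length trend, and other gene choices for a response score that was itself devised after seeing the data.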

Results

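Leaf transcriptomes of 2 melon varieties were compared at the start and after 12 h of exposure to 4 °C. The labels describe 162 as tolerant and 13-5A as sensitive to chilling, and the series asks how their responses differ. Each of the 4 combinations of variety and time had 3 libraries, with recovered totals between 41299369 and 45355323. Libraries of one group correlated at 0.95 to 0.987 over the 15592 tested genes. The median correlation was 0.861 between times of one variety and 0.904 between varieties at one time. The first principal component held 51.7% of the variance and separated the times, and the second held 29% and separated the varieties. The labels name the 4 °C treatment at both times, and 0 h is read here as the unchilled start, which they do not state. No group was kept without chilling until 12 h, so the effect of 4 °C and that of 12 h of elapsed time cannot be separated, and changes below are changes over both.

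In 162, 1441 genes rose and 1654 fell over 12 h at 4 °C. The genes that rose went from 5.0% ± 1.03 to 17.47% ± 2.9 of all FPKM (SD, n = 3), and those that fell went from 10.76% ± 0.9 to 4.0% ± 0.26. The direction of these shares follows from choosing the genes in the same libraries. In 13-5A, whose libraries did not choose them, the same sets went from 4.31% ± 0.54 to 14.9% ± 1.46 and from 10.87% ± 0.23 to 4.68% ± 0.22. MELO3C002315.2 rose from 0.393 ± 0.183 to 115 ± 49.4 FPKM, a log2 difference of 6.30 (SE 0.29, adjusted p = 9.33e-08). MELO3C022429.2 rose from 2.32 ± 0.842 to 211 ± 48.6 FPKM, by 6.0 (SE 0.3, adjusted p = 1.34e-07). MELO3C006819.2 fell from 53.8 ± 26.9 to 1.56 ± 1.23 FPKM (log2 difference -4.44, SE 0.44, adjusted p = 1.23e-05), and MELO3C020752.2 from 34.3 ± 19.3 to 0.72 ± 0.765 (-4.26, SE 0.4, adjusted p = 8.93e-06). The 3095 calls by limma with Benjamini-Hochberg adjustment were 19.8% of the genes tested. Of these, 400 rose and 199 fell at least 4-fold. Median-ratio scaling gave 1593 genes higher and 1359 lower, and removal of the length trend 1569 and 1425. A minimum mean of 5 FPKM gave 1175 and 1158, so the majority turned under each. With median-ratio scaling the median of all genes moved from -0.12 to -0.04. Removal of the length trend also removed each library's mean level, so it tends to even the split as median-ratio scaling does.

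In 13-5A, 1969 genes rose and 1413 fell. The share of FPKM held by the genes that rose went from 5.8% ± 0.43 to 20.35% ± 1.93 (SD, n = 3), and that of the genes that fell from 13.21% ± 0.32 to 4.7% ± 0.41. These directions too follow from the choice of genes. In the libraries of 162 the same sets went from 9.39% ± 2.2 to 22.46% ± 3.71 and from 9.07% ± 0.44 to 4.14% ± 0.41. MELO3C026611.2 rose from 7.48 ± 4.73 to 428 ± 104 FPKM (log2 difference 5.77, SE 0.53, adjusted p = 5.05e-06), and MELO3C011223.2 from 4.86 ± 3.7 to 243 ± 20.1 (5.66, SE 0.57, adjusted p = 1.01e-05). MELO3C029545.2 fell from 338 ± 64.2 to 8.22 ± 3.05 FPKM (-5.23, SE 0.27, adjusted p = 1.3e-07), and MELO3C026601.2 from 125 ± 34.5 to 3.06 ± 1.42 (-4.99, SE 0.44, adjusted p = 3.74e-06). The 3382 calls by limma were 21.7% of the genes tested, and 485 rose and 233 fell at least 4-fold. Under median-ratio scaling 1731 were higher and 1703 lower. With the gene length trend removed 1671 were higher and 1731 lower, which turned the majority. That step also removed each library's mean level, so the turn is not evidence of a gene length effect. Spearman's rho of the log2 difference with gene length was 0.032.

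**Figure D1:**
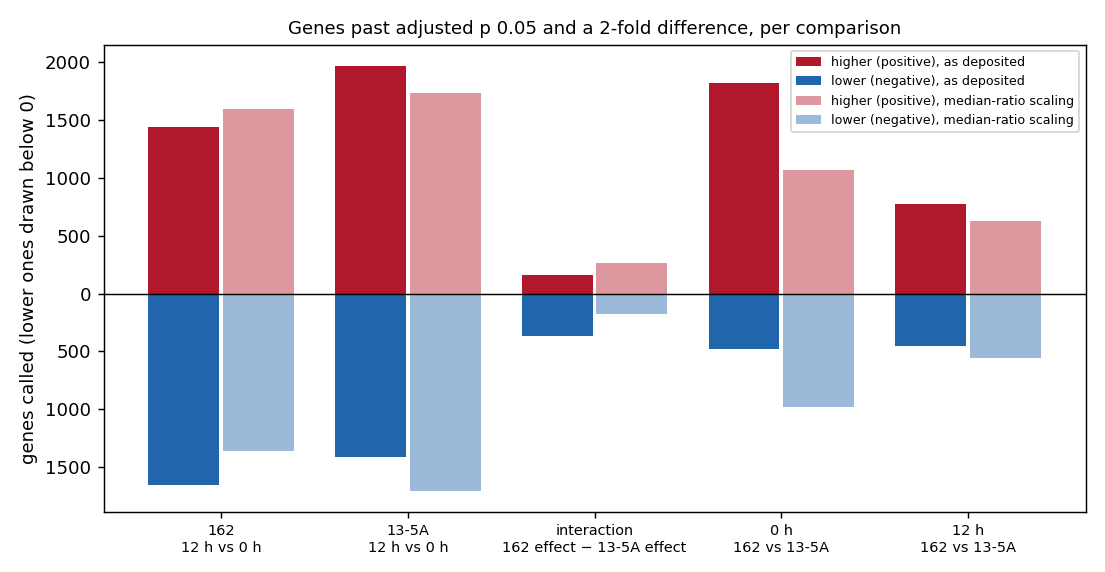
Number of genes called in each of the 5 comparisons, drawn upward where higher or positive and downward where lower or negative. Dark bars use the deposited FPKM and pale bars median-ratio scaling. At 0 h, 1821 genes were higher and 481 lower in 162 with the former, and 1071 and 981 with the latter, not all of them the same genes.

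The varieties shared much of the response. Of the genes that rose, 1112 rose in both varieties, where independent lists would share 182. Of the genes that fell, 913 fell in both, where 149.9 would be shared. MELO3C026611.2, MELO3C011223.2, MELO3C020752.2 and MELO3C026601.2 are among those called alike. Across genes, which are not independent replicates, the log2 differences of the varieties correlated at r = 0.824 (Spearman's rho 0.796), and the comparisons share no library. A further 1065 genes were called in 162 without being called in 13-5A, and 1352 the other way round. The interaction was called for 152 of the former and 182 of the latter, so for the rest a difference between varieties was not shown.

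The change over 12 h differed between varieties in 532 genes by the interaction test of limma. MELO3C029545.2 fell in both but less in 162, from 279 ± 93.9 to 87.8 ± 17.4 FPKM, than in 13-5A, from 338 ± 64.2 to 8.22 ± 3.05 (interaction 3.61, SE 0.39, adjusted p = 0.000746). MELO3C002739.2 rose in 162 from 0.63 ± 0.809 to 20.7 ± 5.86 FPKM and was at 0.0106 ± 0.0184 and 0.138 ± 0.121 in 13-5A (interaction 3.63, SE 0.41, adjusted p = 0.000889). MELO3C024499.2 rose in 13-5A from 6.96 ± 5.42 to 110 ± 20.8 FPKM, while 162 had 15 reads in all at 0 h and 7 at 12 h (interaction -4.22, SE 0.74, adjusted p = 0.0118). MELO3C012505.2 fell in 162 from 120 ± 57.3 to 11 ± 4.79 FPKM and had 0 reads at 0 h and 27 at 12 h in 13-5A (interaction -3.94, SE 0.64, adjusted p = 0.00874). Of the 532 interactions, 370 were negative and 162 positive. Median-ratio scaling called 445, 180 negative and 265 positive, as the median of all genes moved from -0.16 to 0.01. Of the 532, 342 were called in the same direction under both scalings, so the genes changed as well as the split. The count fell to 258 without replicate 2 of 162 at 12 h, to 178 and 310 without replicates 1 and 3 of 13-5A at 0 h, and to 225 and 324 without replicates 1 and 2 of 13-5A at 12 h. With limma voom on the recovered reads, MELO3C002739.2, MELO3C024499.2 and MELO3C012505.2 were no longer called (adjusted p = 0.271, 0.381 and 0.14), with interactions of 3.72 (SE 1.85), -5.37 (SE 3.36) and -5.89 (SE 2.14).

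**Figure D2:**
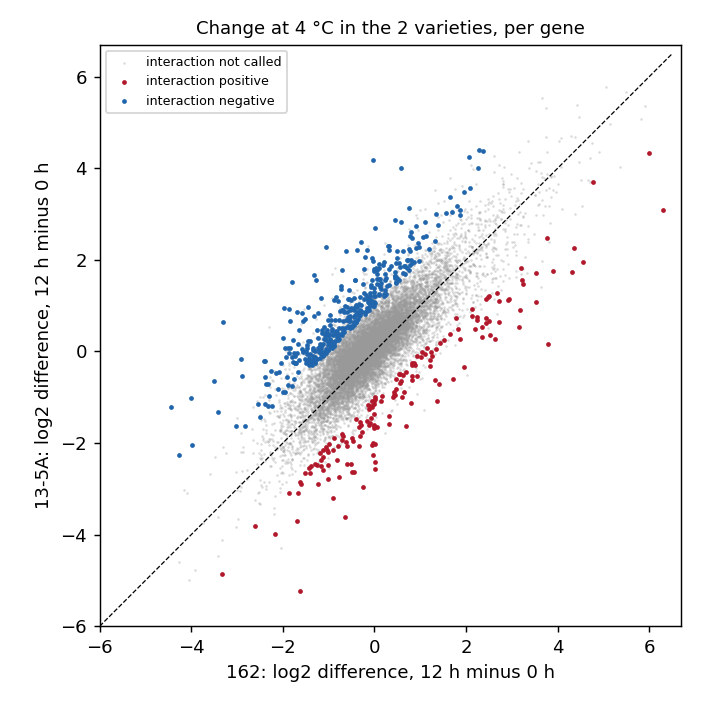
Log2 difference between 12 h and 0 h for each tested gene, in 162 on the horizontal and in 13-5A on the vertical axis, with equality as a dashed line. Coloured points are the 532 genes with a called interaction, red where positive and blue where negative.

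Only 5 genes were called in opposite directions in the varieties, and they are named after their values were seen. MELO3C017480.2 fell in 162 from 216 ± 113 to 59.1 ± 21.5 FPKM and rose in 13-5A from 91.7 ± 14.8 to 267 ± 62.4. MELO3C016588.2, MELO3C005466.2 and MELO3C016595.2 moved the same way, with log2 differences of -1.32 (SE 0.37), -1.29 (SE 0.39) and -1.16 (SE 0.23) in 162 and 1.67, 1.55 and 1.18 in 13-5A. MELO3C020143.2 did the reverse, rising in 162 from 21.7 ± 9.13 to 57.2 ± 21.5 FPKM and falling in 13-5A from 30.6 ± 8.74 to 14 ± 3.97. The interaction adjusted p from limma lay between 0.00409 and 0.0248 for these genes.

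**Figure D3:**
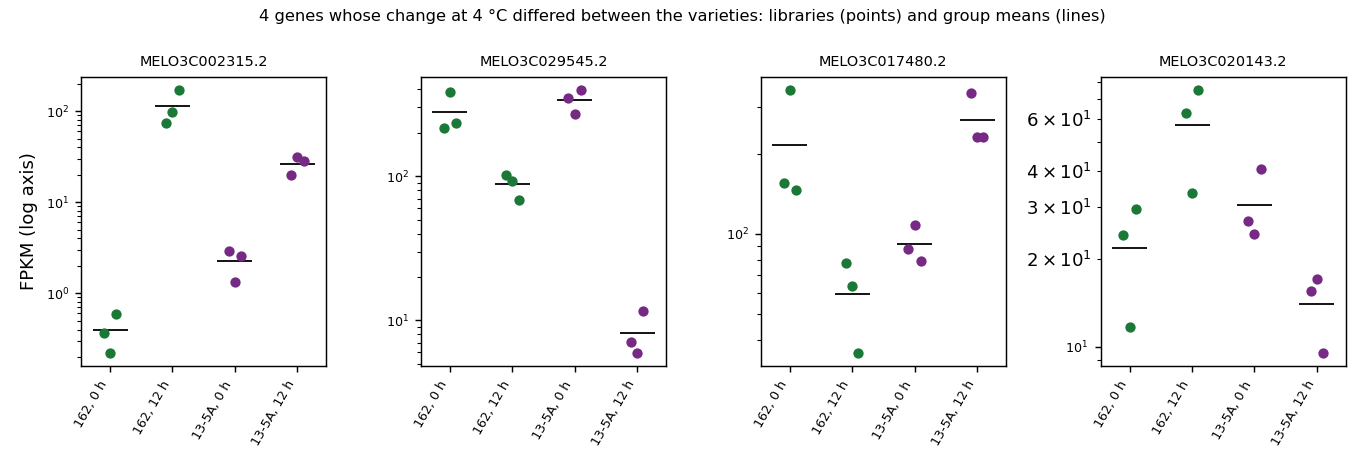
FPKM on a log axis in each library (points) and group means (lines) for 4 genes whose change differed between varieties. MELO3C002315.2 rose more in 162, MELO3C029545.2 fell more in 13-5A, and MELO3C017480.2 and MELO3C020143.2 went opposite ways.

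At 0 h, 1821 genes were higher and 481 lower in 162 than in 13-5A. MELO3C012505.2 stood at 120 ± 57.3 FPKM in 162 (SD, n = 3) and had 0 reads in 13-5A, so it was at least 418-fold higher, counting 3 reads per library as the floor. MELO3C002437.2 stood at 137 ± 84.3 against 0.145 ± 0.175 FPKM (log2 difference 6.76, SE 0.58, adjusted p = 6.96e-06). MELO3C032345.2 had 0 reads in 162 and 108 ± 5.22 FPKM in 13-5A, at least 1146-fold lower in 162. MELO3C031806.2 had 1 read in the 3 libraries of 162 and 102 ± 11.4 FPKM in 13-5A. The folds above compare reads assigned to a gene, and the floor covers counting error only. The reference is not named, and whether reads of a variety failed to map to these genes was not tested. The most abundant gene, MELO3C012252.2, chosen after its values were seen, took 5.23% ± 0.51 of reads in 162 and 9.78% ± 1.22 in 13-5A (log2 difference -0.90, SE 0.3, adjusted p = 0.0299), short of the 2-fold minimum, and was called under median-ratio scaling (-1.21, adjusted p = 0.014). Calls by limma numbered 2302. Median-ratio scaling moved the share of calls higher in 162 from 79.1% to 52.2% (1071 higher, 981 lower), as the median of all genes moved from 0.24 to -0.03. Of the 2302 calls, 1552 were made in the same direction under both scalings.

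At 12 h, 775 genes were higher and 456 lower in 162. MELO3C002437.2 stood at 112 ± 32.8 against 2.63 ± 3.62 FPKM in 13-5A (log2 difference 5.4, SE 0.58, adjusted p = 5.69e-05), and MELO3C015002.2 at 165 ± 35.1 against 5.21 ± 3.03 (4.86, SE 0.41, adjusted p = 8.53e-06). MELO3C024499.2 stood at 0.0255 ± 0.0176 FPKM in 162 and 110 ± 20.8 in 13-5A (-6.74, SE 0.52, adjusted p = 3.84e-06). MELO3C019363.2 had 3 reads in the 162 libraries and 45.9 ± 11.2 FPKM in 13-5A. Of the genes higher in 162 at 0 h, 514 were higher at 12 h too, where independent lists would share 90.5. Of the genes lower in 162 at 0 h, 219 were lower at 12 h too, where 14.1 would be shared. Calls by limma numbered 1231. Under median-ratio scaling 624 were higher and 561 lower, 52.7% in place of 63%.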

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

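The shuffling of residuals described here was chosen after the first regrouping result was seen. The effects of 12 h at 4 °C differed between 162 and 13-5A in 532 genes by the interaction test of limma, which is why this count and the genes below are singled out. MELO3C002315.2, MELO3C022429.2 and MELO3C006819.2, all named for their change in 162, had interactions of 3.21, 1.68 and -3.22. MELO3C029545.2 and MELO3C002739.2 had 3.61 and 3.63, and MELO3C024499.2 and MELO3C012505.2 had -4.22 and -3.94. Of these, MELO3C002739.2, MELO3C024499.2 and MELO3C012505.2 had few reads in a variety and were not called with voom. In 13-5A, MELO3C002739.2 had 1 read at 0 h and 13 at 12 h, so its small change there depends on the pseudocount. MELO3C032345.2 and MELO3C031806.2, with almost no reads in 162, had 1.72 and 1.99, which reflect falls in 13-5A. The genes that moved in opposite directions had -3.33 (MELO3C017480.2), -3.0 (MELO3C016588.2), -2.84 (MELO3C005466.2), 2.45 (MELO3C020143.2) and -2.34 (MELO3C016595.2). Benjamini-Hochberg adjusted p-values ran from 0.000411 for MELO3C032345.2 to 0.0433 for MELO3C022429.2.

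In 5 of 100 regroupings of the varieties within each time, the real one included, as many as 532 genes had an interaction, so chance was not excluded by this count. The highest other count was 2597, and each of the larger ones exchanged 2 libraries between varieties at 12 h and none at 0 h. Such an exchange turns the difference between varieties, a structure of the samples, into an interaction, so this count bears little on chance either way. With variety and time effects kept and only the residuals shuffled, 1 of 100 arrangements, the real one, reached 532. The highest other gave 520, a narrow margin. The residuals came from a fit without the interaction and still held it, so a shuffle can recreate part of it. The 520 is therefore not a count of false calls, and how many of the 532 arose by chance was not measured. For the other counts the 10 splits of 6 libraries are too few for a share under 0.05. Real counts of 3095, 3382, 2302 and 1231 stood against highest other counts of 0, 0, 0 and 2, each real split being the 1 of 10.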

How the results depend on the processing

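The voom fit, the rescaling without the 10 highest genes, the removal of the length trend and the other gene choices for the response score were chosen after seeing the data. Of 809 values under alternatives, 746 stayed within 1.5 times the count, within the replicate spread or on their side of the threshold, 59 moved, 3 calls were lost and 1 sign turned. Of the 809, 380 were for the 20 named gene differences, chosen as the largest, and some alternatives leave these unchanged by construction. The tally therefore overstates stability, and it does not register a turned majority of higher or lower genes. Without the fold minimum the counts became 7719 and 7770 for 12 h against 0 h in 162 and 13-5A, and 6523 and 3449 for the varieties at 0 h and 12 h, by construction. The response score, defined below, changed by 3.50 in 162 and 3.68 in 13-5A. These changes became 3.89 and 4.11 with pseudocount 0.1, and 2.34 and 2.48 without the fold minimum. With voom they were 3.99 and 4.26. Over the genes called in 162 they were 3.26 and 2.82, and over those called in 13-5A 2.56 and 3.28. The score's difference between varieties at 0 h, 0.50, became -0.02 and 0.84 over those gene choices. Apart from the gene choice, which sets the score by construction, the cause was not tested.

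Leaving out each library gave 2854 to 3506 calls in 162, 3166 to 3561 in 13-5A, 2176 to 2454 at 0 h and 981 to 1419 at 12 h. The interaction count ran from 178 to 657, and fell by over 1.5 times to 258 without replicate 2 of 162 at 12 h, 178 and 310 without replicates 1 and 3 of 13-5A at 0 h, and 225 and 324 without replicates 1 and 2 of 13-5A at 12 h. Score changes ran from 3.48 to 3.59 in 162 and from 3.62 to 3.77 in 13-5A, and the 0 h difference from 0.32 to 0.56. The 3 lost calls were interactions under voom: adjusted p = 0.271 for MELO3C002739.2, 0.381 for MELO3C024499.2 and 0.14 for MELO3C012505.2, against at most 0.0315, 0.037 and 0.0405 under the other alternatives. The log2 differences were no smaller, at 3.72, -5.37 and -5.89, and the calls ended because the SE widened from 0.41, 0.74 and 0.64 to 1.85, 3.36 and 2.14.

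Replicate numbers do not pair the samples: deviations in 18 pairs with the same number correlated at -0.31 to 0.31, with 2 over 0.1. The replicate block gave 3077, 3377, 367, 2302 and 1208 calls in the order 162, 13-5A, interaction, 0 h and 12 h. The alternatives for gene lists were not run, since no identifier matched a name, and the fit with only the compared groups cannot be made for the interaction. Depth limits genes with few reads: 1 FPKM is about 72 reads at the median length, and fewer in shorter genes.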

Other observations

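Several genes had almost no reads in a variety at both times, by limits of 0.1 and 5 FPKM chosen after seeing the data. Whether this reflects expression or reads that failed to map was not tested. In 23 genes the 6 libraries of 162 were all below 0.1 FPKM and the 6 of 13-5A all at 5 or above, with a median of 14.8 FPKM in 13-5A and a range of 8.06 to 70.5. The reverse held for 2 genes: MELO3C012540.2 had 11.5 ± 6.47 FPKM in 162 (SD over 6 libraries) and MELO3C035515.2 15.2 ± 6.26, with at most 0.0913 and 0.0567 FPKM in any 13-5A library.

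MELO3C027448.2 had the widest spread within groups among 1060 genes with a mean of at least 100 FPKM, a choice made after seeing the data. It ran from 428 to 8921 FPKM, both in 162 at 0 h, and its within-group SD was 1.66 on the log2 scale against a median of 0.28 for these genes.

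In what follows, the tests of replicate spread and time of day were chosen after the results they measure were seen. Median-ratio scaling and leaving out each library were planned, but the limits by which they are read here, and the response score itself, were set after seeing the data, and the rescaling without the 10 highest genes and the length correction were added after seeing the data. At 0 h, 79.1% of calls were higher in 162 than in 13-5A. Under median-ratio scaling the share was 52.2%, and with the length trend removed 52.1%. Both steps centre the genes in each library and so even the split largely by construction. The scaling of the deposited values and a gene length trend stay open as sources. The 10 highest genes of each library took 11.2% ± 0.6 of reads in 162 and 19.0% ± 1.1 in 13-5A. The rescaling instead left out a fixed set, the 10 genes highest on average over the 12 libraries, and gave 69.2%. This lay between the limits of 60 and 70 set before that value was seen. How much of the imbalance the fixed set explains therefore cannot be told apart. Which scaling is nearer to RNA per cell stays open, and no biological explanation of the imbalance was tested.

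More genes differed between the varieties at 0 h (2302) than at 12 h (1231), a ratio of 1.87. The ratio was 1.73 under median-ratio scaling and 1.69 with the length trend removed, which argues against both as the whole cause. The within-group SD at 0 h was 1.07 times that at 12 h, and the main fit shares its spread over all groups. With each time fitted on its own spread the ratio was 1.85, so a smaller spread at 0 h is not the reason. A hypothesis is that chilling brings the varieties' transcriptomes closer, but with 0 unchilled groups at 12 h it cannot be told apart from time of day.

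A response score, the mean log2 level of the 1112 genes that rose in both varieties minus that of the 913 that fell in both, was -1.0 ± 0.3 in 162 and -1.49 ± 0.08 in 13-5A at 0 h (SD, n = 3), and 2.51 ± 0.18 and 2.19 ± 0.16 at 12 h. The 0 h difference was 0.50 (SE 0.18; exact permutation p = 0.1, two-sided, the smallest 3 against 3 libraries allow). At 12 h it was 0.31 (SE 0.14, exact permutation p = 0.2), and the change in 13-5A exceeded that in 162 by 0.18 (SE 0.23, not tested), so whether 162 lies nearer to the chilled state at 0 h or scores higher at both times stays open. With genes chosen without the scored libraries the mean difference over 9 pairs was 0.52 (0.17 to 0.94), which argues against the same libraries choosing and scoring the genes; the use of all 9 pairs, and of a margin beyond the SE, was decided after a first run on same-numbered pairs, which also gave 0.52. Without replicate 2 of 162 at 0 h it was 0.32 (SE 0.12), so one library stays open as a part of it, and the difference with all libraries depended on the genes, at -0.02 over genes called in 162 and 0.84 over genes called in 13-5A, and 0.09 and 0.76 with the scored libraries left out of the choice.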
